A study of Halobacterium salinarum NRC-1 with 48 samples.

How the data were processed

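RNA levels were measured in the archaeon Halobacterium salinarum NRC-1 with printed 2-colour arrays. Each of the 48 samples was hybridised on 2 arrays with the dyes exchanged, against a common reference of RNA from a standard mid-logarithmic culture. The description of each sample names the dye that carried the sample on each of its arrays, so the direction of every ratio is settled per the labels.

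The deposited scanner tables hold the linear fluorescence intensity of each spot and of its local background in both channels, for 10752 spots on each of 96 arrays, with no probe names. A second deposited table holds the authors' processed values for 2400 probes in the 48 samples, on a log scale. The authors' values lay nearest to log10 ratios of sample over reference, each made from the 2 arrays of a sample, with a median ratio of 0.308 between their SD and that of the log2 ratios computed here; the log base is not stated in the labels. Wherever a change is given with the authors' values, it was converted from log10 to log2, so its size rests on that reading of the base, while its sign and the counts of called probes do not. Column medians of the authors' table ran from -0.02 to 0.14, and its values correlated positively with the ratios computed here in all 48 samples (median r across probes 0.642, lowest 0.356). How the authors normalised and centred them is not given in the sources used here.

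Spots were assigned to probe IDs by a printing rule worked out by matching the spots to the authors' table. The rule takes 7 plates of 384 wells, printed with 24 pins, each well at 4 spots. Under it, the median correlation over the 48 samples between a probe and its own row of the table was 0.391, against 0.042 with the rule moved by 1 pin dip. Of the 2400 probes, 284 correlated better with their own row than with any other row of the table, against 2 under the moved rule, so single probes are mostly not pinned by this check alone. Each of the 24 print blocks matched its own assignment better than that of any other block, and so did 108 of the 112 dips. The 288 positions that the table leaves out had a median signal over background of 104.0, against 383 at the other positions. The IDs are therefore inferred, and a fault in the rule for single wells cannot be excluded. The files do not pair the probe IDs with genes: the reference gene table, which is of another strain of the species, holds locus tags and no probe IDs, and was not used here. No gene is named here, the keyword lists of genes fixed before the data were examined could not be applied, their camera tests were not run, and the deleted genes could not be checked in the strains.

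For each array, the spot means were corrected with the local background by normexp with an offset of 50, and log ratios were normalised within the array by loess, with the 288 positions given no weight. The 4 spots of a probe were averaged (median SD between them 0.273 on the log2 scale), the exchanged array was turned, and the 2 arrays of a sample were averaged to 1 value, log2 of sample over reference. The median spot lay below its local background in at least 1 channel on 20 arrays, so that dim probes there carry little information. Between arrays of the same dye orientation the median r was 0.506 and the lowest -0.0129.

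The samples fall into 28 groups of strain, iron and time, with 1 to 3 samples each. limma (version 3.58.1, R 4.3.3) fitted the mean of each group over all 48 samples with 20 residual degrees of freedom. Contrasts between group means, each averaged over the sampling times with equal weight, were tested with moderated statistics. P-values were 2-sided and adjusted by the Benjamini-Hochberg method over the 2400 probes within each contrast, with a threshold of 0.05 on the adjusted p. Every group of the Δidr1 strain holds 1 sample, which is assumed to vary like the replicated groups. The labels give replicate time courses and do not say more about how separate the cultures were, so p-values measure the spread between these samples. The number of arrays limits the precision.

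Samples with the same number within a strain were compared through the difference between replicates 1 and 2 in each group. These differences correlated across probes between all groups of Δidr2 (21 correlations, from 0.208 to 0.796) and of the double mutant (15 correlations, from 0.33 to 0.823). In the parent 7 of 10 exceeded 0.1, with a lowest value of -0.08. The numbers thus pair the samples in the double mutant, and the series text speaks of replicate time courses. In Δidr2 every replicate 1 lies in array series 3 and every replicate 2 in array series 4, as numbered below. There a shared course and a shared array series cannot be told apart. The main fit has no term for the time course and treats its times as independent. Where samples of a course go together, the SEs and adjusted p-values of strain comparisons therefore tend to be too small. Those of the iron responses, and of their differences between strains, tend to be too large where both parts of a split course were sampled. The difference between courses cancels there but stays in the spread. A low count of called probes in these tests is thus weak evidence of no response.

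The array numbers fall into 4 series, called array series 1 to 4 here in order of number. Series 1 holds 3 samples of Δidr1 and 2 of the parent, series 2 holds 2 of the parent, series 3 holds 4 of Δidr1, 7 of Δidr2 and 1 of the parent, and series 4 holds all 14 of the double mutant, 8 of Δidr2 and 7 of the parent. Δidr1 and the double mutant therefore share no series.

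A rule fixed before the data were examined named genes in order of the size of their change. It took those past the threshold with the same sign at every time averaged, and left probes that name no gene unnamed. Because no gene names are paired with the IDs, that rule would name none. In a departure from it, at most 2 higher and 2 lower probes are named for a comparison, in the same order. Any other probe is said to have been chosen after its values were seen. Alternatives fixed before the data were examined were no background correction, median centring in place of loess, leaving out the dimmest 25% of probes, scaling between arrays, the authors' values, a replicate block, the array series as a random block, only the samples of the compared strains, and leaving out each sample in turn. Added after seeing the data were the array series as a fixed block, series 4 alone, leaving out the 8 samples whose dye-exchanged arrays correlated under 0.5, the mean iron response of the strains, the contrasts between the mutants, the calls of Δidr1 made without series 1, and the set means within single series.

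The fit was tested on simulated arrays in which 200 of 2400 probes were changed. It recovered 85 of 100 probes changed by 1 log2 unit in the parent's iron response, 79 in that of Δidr1, 96 in that of Δidr2 and 93 in that of the double mutant. For the difference of the iron response it recovered 62, 65 and 66 of 100 in Δidr1, Δidr2 and the double mutant. Across the comparisons, false calls made up 1.65% to 7.65% of the calls. camera found a simulated shift of 0.3 in 90 probes of the parent's iron response in 20 of 20 simulations and called no unchanged set. The simulated errors were independent between probes and samples, with no array series and no time course. In the data the correlation within array series was 0.466, so these rates need not hold there. The L scans of each dye and the positions outside the table were not used in the comparisons.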

Results

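The study followed RNA levels after iron was given back to iron-starved cells of Halobacterium salinarum, a salt-loving archaeon, in a parent strain lacking ura3 and in strains that also lack idr1, idr2 or both. The study's title is about transcription factors needed for iron homeostasis. Cultures grown without iron were split, iron sulfate (100 µM per the labels) was added to one part, and both parts were sampled at 20, 40 and 60 min; a sample at 0 min was taken before the addition. There are 12 samples of the parent, 7 of Δidr1, 15 of Δidr2 and 14 of the double mutant. Values are log2 of sample over a common reference, and a change of 1 is 2-fold. The correlation between the 2 dye-exchanged arrays of a sample ran from 0.189 to 0.894. All 8 samples under 0.5 were of Δidr2. The arrays of the double mutant were the dimmest, with a median reference signal of 136 over background against 640 in the parent, and their log2 ratios had a smaller SD across probes (median 0.45 against 0.63). After 0 min, the difference between the 2 samples of a group had an SD across probes of 0.24 to 0.36 in the double mutant. It was 0.53 to 0.65 in the parent and 0.51 to 0.67 in Δidr2, and in these strains the 2 samples lie in different array series. The fit pools the spread over all strains, so counts of called probes do not compare the size of the response between strains.

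The double mutant responded to iron with 90 probes that rose and 94 that fell. HO06J23 rose most, by 2.40 on the log2 scale (SE 0.30, adjusted p 1.12e-05), or 5.28-fold. Its level was -0.83 ± 0.13 (SD, n = 5) without iron and 1.57 ± 0.25 (SD, n = 6) with iron, and every sample with iron lay above every sample without. HO05N02 rose by 1.66 (SE 0.32, adjusted p 0.00163). The largest falls were in HO05A16, at -1.15 (SE 0.22, adjusted p 0.00135), and HO01J02, at -1.08 (SE 0.21, adjusted p 0.00186). Of the 184 probes, 19 changed more than 2-fold, and the median size was 0.67. HO06J23 was already up by 2.25 at 20 min and stood at 2.55 and 2.40 at 40 and 60 min. By the single times, the test called 0 probes at 20 min (90 at an unadjusted p under 0.05), 6 at 40 min and 28 at 60 min.

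With the replicate block, under which samples of a time course are compared with each other, the double mutant's count was 315. Median centring in place of loess gave 83 risen and 19 fallen probes, so the balance of rises and falls rests on the normalisation. The count was 122 without replicate 1 at 20 min without iron and 75 without the lone sample at 40 min without iron, whose loss removes that time. All samples of this strain lie in array series 4.

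**Figure D1:**
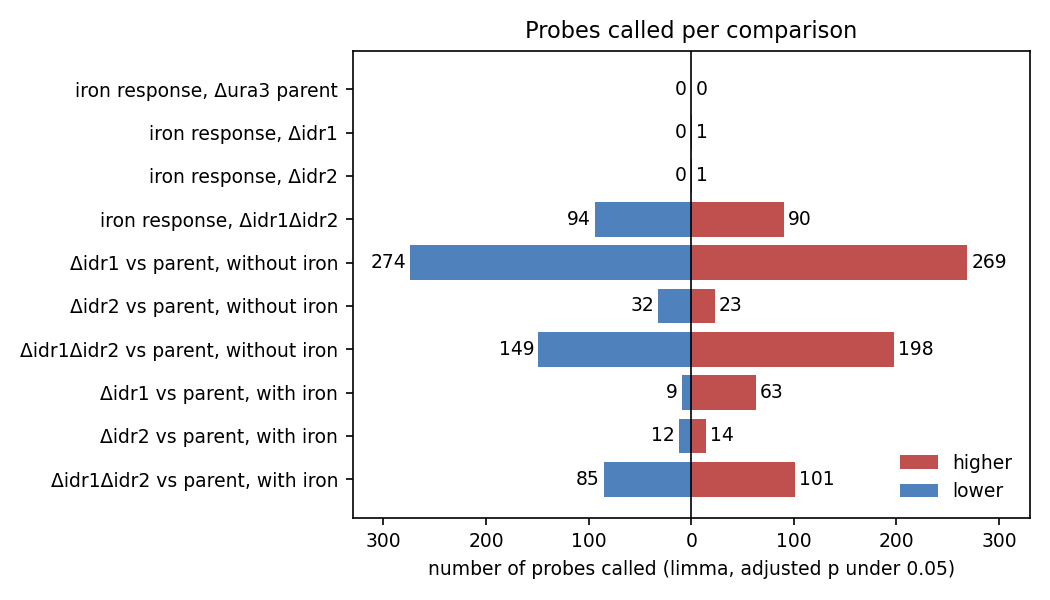
Number of probes called higher (right) or lower (left) in each comparison, on an axis of probe counts, by limma at an adjusted p under 0.05. The iron response called 184 probes in the double mutant and at most 1 in the other strains, and Δidr1 without iron had 269 higher and 274 lower probes than the parent. The strains differ in the spread between replicates, so these counts are not a test between strains.

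In the parent, no probe passed the test for the iron response with limma, and 143 had an unadjusted p under 0.05, where chance would give 120. HO06J23, chosen here because it led the response of the double mutant, changed in the parent by 0.74 (SE 0.32, adjusted p 0.811), with 0.13, 0.47 and 1.63 at 20, 40 and 60 min. The count of 0 held with the authors' values and each other normalisation, but the number at an unadjusted p under 0.05 did not: it was 766 with the authors' values, 314 with the series as a fixed block and 309 in series 4 alone, so a weak response in the parent is not excluded. It was 8 with the replicate block, 4 with the array series as a random block and 41 with the series as a fixed block, and 1 without replicate 2 at 60 min without iron. Within single array series, the parent's responses correlated across probes with that from all series at 0.266 in series 1 (20 min), 0.475 in series 2 (60 min) and 0.627 in series 4 (20 and 40 min); probes are not independent replicates, and each series is part of the whole.

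In Δidr1, HO05M05 was the only probe that passed, with a rise of 1.00 (SE 0.18, adjusted p 0.0173), and 208 probes had an unadjusted p under 0.05. The rise of HO05M05 was 0.11 within array series 1 (20 min) and 1.44 within series 3 (40 and 60 min). The call was lost without either sample at 40 min (0.69) or either at 60 min (0.86), without background correction (0.29), with scaling between arrays (0.69) and with the authors' values (0.29). HO06J23 changed by 1.44 in this strain (SE 0.39, adjusted p 0.213). There was no replicate, and 15 probes passed with the array series as a random block.

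In Δidr2, HO05K03 was the only probe that passed, with a rise of 0.90 (SE 0.16, adjusted p 0.0132), and 181 probes had an unadjusted p under 0.05. It rose by 0.59 in the double mutant as well (SE 0.17, adjusted p 0.0314). HO05K03 was up by 1.31 within array series 3 and by 0.50 within series 4, and lost its call in many fits: without background correction (0.52), with median centring (0.79), with scaling between arrays (0.80), with the authors' values (0.35), with only its own strain's samples, without the 8 samples whose arrays agreed poorly (0.29) and in 6 of 12 fits that left out a sample. HO06J23 changed by 0.78 (SE 0.28, adjusted p 0.566) in this strain. The replicate block gave 4 probes. Series 4 alone, a choice made after seeing the data, gave 249 risen and 262 fallen probes with 9 residual degrees of freedom, for which Δidr2 itself gives a replicate only at 0 min. Without the 8 samples the count was 45, and HO05K03 was not among them. Left out one at a time, replicate 1 at 40 or 60 min without iron, both samples at 40 min with iron, and replicate 1 at 60 min with iron each took the count to 0; without replicate 1 at 20 min with iron it was 3 and without replicate 2 at 60 min with iron 2.

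Most of the probes called in the double mutant changed in the same direction in the other strains, though 1 of them at most was called in any of these. Of the 90 that rose there, 83 were positive in the parent, 82 in Δidr1 and 84 in Δidr2, against 49.3%, 47.5% and 51.3% of all probes. Their mean response was 0.30 in the parent, 0.42 in Δidr1 and 0.24 in Δidr2, and 0.78 in the double mutant, where they had been selected for size. Of the 94 that fell, 78, 86 and 82 were negative, with means of -0.19, -0.22 and -0.20. camera, which compares a set with all other probes, gave adjusted p = 1.02e-28, 3.34e-29 and 1.87e-19 for the risen set in the parent, Δidr1 and Δidr2 with its preset correlation. With an estimated correlation these were adjusted p = 2.98e-07, 2.98e-07 and 4.65e-06. For the fallen set the largest of the 3 was adjusted p = 0.000842 with an estimated correlation. The means depended on the processing: with the authors' values, converted to log2 as log10 ratios, the risen set stood at 0.14, 0.21 and 0.07 in the parent, Δidr1 and Δidr2, and with median centring the fallen set stood at -0.03 in the parent and -0.11 in Δidr1. camera was run on the main values alone. The comparison was chosen after seeing the data, but the samples of the other strains had no part in choosing the set beyond the shared estimate of spread.

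The response of the risen set was larger at 60 than at 20 min in the parent, Δidr1 and Δidr2. It stood at 0.09, 0.35 and 0.46 in the parent at 20, 40 and 60 min, at 0.23, 0.51 and 0.54 in Δidr1 and at 0.06, 0.22 and 0.43 in Δidr2. In the double mutant it was 0.50 at 20 min, 0.94 at 40 min and 0.90 at 60 min. The rise from 20 to 60 min, relative to other probes, had adjusted p = 0.000272, 0.000515 and 0.000272 in the parent, Δidr1 and Δidr2 with an estimated correlation. For the fallen set, whose change from 20 to 60 min was -0.19, -0.30 and -0.15, these were adjusted p = 0.055, 0.00425 and 0.0638, and with the preset correlation adjusted p = 0.000289, 7.25e-09 and 0.000711. Time and array series coincide in part. Both series of Δidr2 hold every time, and there the risen set stood at 0.14, 0.35 and 0.46 in series 3 and at -0.02, 0.10 and 0.39 in series 4. Within series 4 of the parent, which holds samples both with and without iron only at 20 and 40 min, the risen set went from 0.03 to 0.32 and the fallen set from -0.07 to -0.23. In the parent and Δidr1 no series holds samples both with and without iron at 20 and at 60 min. The change from 20 to 60 min and the series therefore cannot be told apart there.

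**Figure D2:**
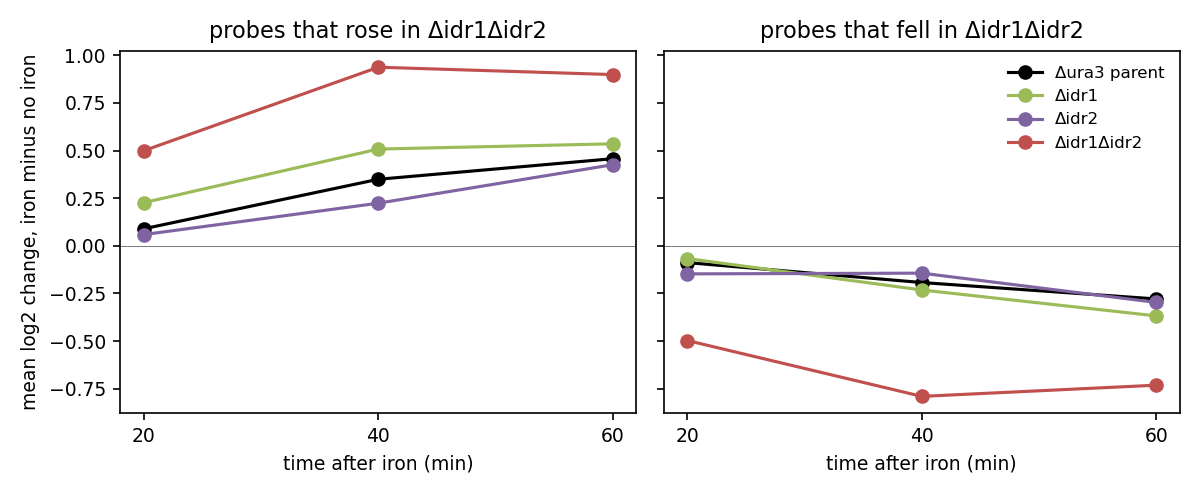
Mean log2 change, iron minus no iron, of the 90 probes that rose (left) and the 94 that fell (right) in the double mutant, against time in min, with a line for each strain. At 60 min the risen probes stood at 0.46 in the parent, 0.54 in Δidr1, 0.43 in Δidr2 and 0.90 in the double mutant, from which they were selected.

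The test of the difference in iron response between a mutant and the parent called no probe by limma in any of the 3 mutants. At an unadjusted p under 0.05 there were 103 probes for Δidr1 and 63 for Δidr2, and for the double mutant 9 more than the 120 of chance. The counts under 120 may reflect SEs that are too large, so they do not show equal responses. In this fit no probe is thus shown to respond differently in the double mutant and the parent. The larger responses of the double mutant given above are of probes selected in that strain. The count of called probes depended on the processing in the double mutant, with 29 probes without background correction, 137 with scaling between arrays, 9 with the authors' values and 5 with the replicate block. It was 10 without the parent's replicate 2 at 60 min without iron, 2 without the parent's replicate 2 at 40 min with iron and 1 without the double mutant's replicate 2 at 60 min with iron. The response of HO06J23 was larger by 1.66 in the double mutant than in the parent (SE 0.44, adjusted p 0.178).

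**Figure D3:**
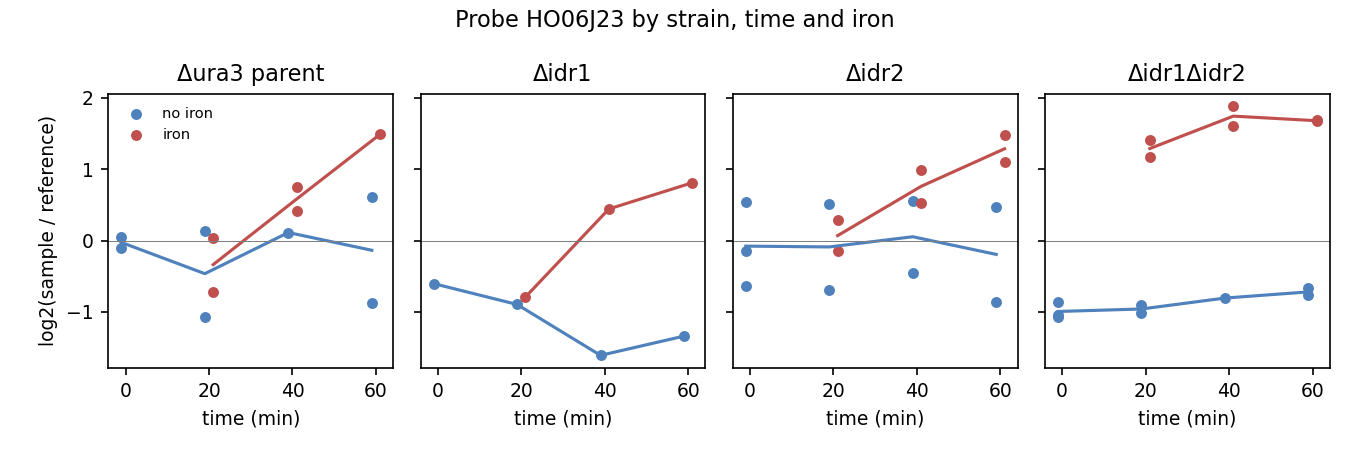
Log2 of sample over reference for probe HO06J23 against time in min, for each strain; points are samples and lines join group means, with iron in red and without iron in blue. In the double mutant the samples with iron lie between 1.18 and 1.89 and those without between -1.08 and -0.67.

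Continued growth without iron, from 0 to the mean of 20, 40 and 60 min over the 4 strains, called no probe with limma, and 81 probes had an unadjusted p under 0.05. A single probe passed without replicate 1 of Δidr2 at 0 min, and likewise 1 without replicate 2 of Δidr2 at 40 min without iron.

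Without iron, Δidr1 differed from the parent in 543 probes, of which 269 were higher and 274 lower. HO05D20 was higher by 2.56 (SE 0.27, adjusted p 8.43e-07), at 2.26 ± 0.24 (SD, n = 4) against -0.28 ± 0.58 (SD, n = 7) in the parent. HO06P08 was higher by 2.31 (SE 0.80, adjusted p 0.0382), and HO06G11 was lower, at -1.96 (SE 0.70, adjusted p 0.0439). HO06A13 was lower, at -1.91 (SE 0.25, adjusted p 1.12e-05), and also in the double mutant, at -1.60 (SE 0.22, adjusted p 2.07e-05), though the authors' values gave 0.08 for its change in Δidr1. The probe was dim, at percentile 25.5 of mean intensity. It stood at -0.02 ± 0.11 (SD, n = 8) in the double mutant, whose arrays were the dimmest. A value near 0 may there be a lack of signal, so a shared loss is not shown. Within array series 1, which holds 1 sample of each strain at 20 min, HO05D20 differed by 1.21, HO06P08 by 1.46, HO06G11 by -0.68 and HO06A13 by -2.46. All samples of Δidr1, with and without iron, are numbered replicate 1. They are thus times of 1 labelled course, and the SD given for Δidr1 is a spread over times. A difference of the strain and a difference of that course cannot be told apart.

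The count for Δidr1 without iron was 264 with the array series as a fixed block and 88 with the authors' values. It was 275 without the Δidr1 sample at 0 min and 347 without the parent's replicate 2 at 20 min. HO06P08 lost its call in 8 of 11 fits that left out a sample and HO06G11 in 9 of 11. With iron, Δidr1 had 63 higher and 9 lower probes than the parent. HO02B12 was higher by 1.68 (SE 0.16, adjusted p 2.49e-07). Its level was 1.57 ± 0.17 (SD, n = 3) in Δidr1 and -0.09 ± 0.28 (SD, n = 5) in the parent. Without iron HO02B12 was higher by 2.08 (SE 0.14, adjusted p 7.02e-11), while in Δidr2 and the double mutant it differed from the parent by 0.06 and -0.24 (adjusted p 0.869 and 0.171). HO02I03 was higher by 1.45 (SE 0.35, adjusted p 0.0188), HO06A13 lower at -1.56 and HO03F24 lower at -1.10 (SE 0.18, adjusted p 0.00198). HO02I03 lost its call in 4 of 8 fits that left out a sample and HO06A13 in 1. Within array series 1 and 3 HO02B12 differed by 1.42 and 1.48. The excess of higher over lower probes with iron was smaller in proportion with the replicate block and with the array series as a random or a fixed block. The count of 72 fell to 8, 13 and 41 without the Δidr1 samples with iron at 20, 40 and 60 min. It was 45, 37 and 41 without the parent's replicate 2 at 20 min, replicate 2 at 40 min and only sample at 60 min, 27 with scaling between arrays, 12 with the authors' values and 1 with only the samples of the compared strains.

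Against the parent, Δidr2 had 23 higher and 32 lower probes without iron. HO02J21 was the lowest, at -3.76 (SE 0.18, adjusted p 6.91e-14), a 13.5-fold difference. Its level was -1.24 ± 0.36 (SD, n = 9) in Δidr2 and 2.46 ± 0.46 (SD, n = 7) in the parent, with no overlap of samples. HO02L21 lay lower by -2.20 (SE 0.19, adjusted p 1.87e-08). HO06I24 was higher by 1.47 (SE 0.14, adjusted p 7.65e-08) and HO02D15 by 0.92 (SE 0.23, adjusted p 0.0283). Within array series 4 these differences were -3.72, -2.37, 1.50 and 0.78. With iron, 14 probes were higher and 12 lower. HO02J21 was again lowest, at -3.35 (SE 0.22, adjusted p 7.39e-11), HO01A09 was lower at -1.62 (SE 0.27, adjusted p 0.00125), HO06I24 was higher by 1.66 (SE 0.17, adjusted p 3.66e-07) and HO02H05 by 0.79 (SE 0.20, adjusted p 0.0479). HO02H05 lost its call in 9 of 11 fits that left out a sample, and HO02D15 without iron in 6 of 16. Within array series 3 and 4 HO02J21 differed by -3.38 and -3.39, HO01A09 by -1.75 and -1.91, HO06I24 by 1.52 and 1.24 and HO02H05 by 1.10 and 0.46.

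Both counts for Δidr2 were unstable. Median centring gave 10 higher and 6 lower probes without iron, and 1 higher and 5 lower with iron, where scaling between arrays gave 18 and 10. The authors' values gave 5 probes without iron and 2 with iron. Without iron, leaving out a sample gave 30 (parent, replicate 2 at 0 min), 29 (parent at 40 min), 87 (parent, replicate 2 at 60 min), 28 or 83 (Δidr2, replicate 1 or 2 at 20 min), 29 or 91 (replicate 1 or 2 at 40 min) and 36 (replicate 1 at 60 min). With iron it gave 9 and 7 without the parent's replicate 1 at 20 and 40 min, 13 without replicate 2 of Δidr2 at 20 min, 15 or 7 without its replicate 1 or 2 at 40 min, and 8 or 52 without its replicate 1 or 2 at 60 min. HO02J21 and HO06I24 kept their calls in all of these fits and in every alternative run.

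The double mutant without iron had 198 higher and 149 lower probes than the parent. HO06P08 was higher by 3.49 (SE 0.69, adjusted p 0.00156), and HO06F16 by 2.04 (SE 0.31, adjusted p 9.32e-05). In both probes the time courses of the double mutant lay apart. HO06P08 was at 2.17 to 2.62 in replicate 1 and at -1.31 to -0.76 in replicates 2 and 3, against -3.30 to -1.73 in the parent. HO06F16 was at 0.91 to 1.39 in replicate 1 and at -0.08 to 0.16 in the others. HO06B15 was lower, at -3.13 (SE 0.43, adjusted p 2.16e-05), and HO04C20 at -2.12 (SE 0.32, adjusted p 8.24e-05). Their levels without iron were 4.26 and 2.14 in the parent and 1.28 and 0.09 in the double mutant. Compressed ratios on the dim arrays of this strain would also pull levels towards 0. For HO06B15 and HO04C20, compression and a strain difference cannot be told apart. With iron there were 101 higher and 85 lower probes. HO06P08 was higher by 3.21 (SE 0.78, adjusted p 0.0119), again with replicate 1 (3.01 to 3.09) apart from replicate 2 (-0.53 to 0.56), and HO06D14 was higher by 2.50 (SE 0.25, adjusted p 6.07e-07), at 0.02 ± 0.34 (SD, n = 6) against -2.60 ± 0.78 (SD, n = 5) in the parent. HO06B15 was lower at -2.33 (SE 0.48, adjusted p 0.00313) and HO04F05 at -1.86 (SE 0.42, adjusted p 0.0063). HO06D14 was higher without iron too, by 2.01 in the double mutant and by 1.38 in Δidr1 (SE 0.26, adjusted p 0.000441), and differed by -0.18 in Δidr2 (SE 0.21, adjusted p 0.728).

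Within array series 4, the difference between double mutant and parent without iron was 3.60 for HO06P08, 2.11 for HO06F16, -3.34 for HO06B15 and -2.20 for HO04C20. With iron it was 4.49 for HO06P08, 3.51 for HO06D14, -3.12 for HO06B15 and -0.47 for HO04F05. The double mutant's arrays were dimmer than the parent's in this series too, so the comparison does not remove compressed ratios. This leaves HO06B15, HO04C20 and HO06D14 open, whose levels lay nearer 0 in the double mutant. How many of the calls against the parent come from compression was not tested. Without iron, median centring gave 167 higher and 245 lower probes, so the excess of higher probes rests on the normalisation. With iron the count was 122 and 96 without the parent's replicate 1 at 40 min and only sample at 60 min, and 101 and 108 without replicate 2 of the double mutant at 20 and 40 min, and without that at 60 min it was 55 higher and 47 lower.

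**Figure D4:**
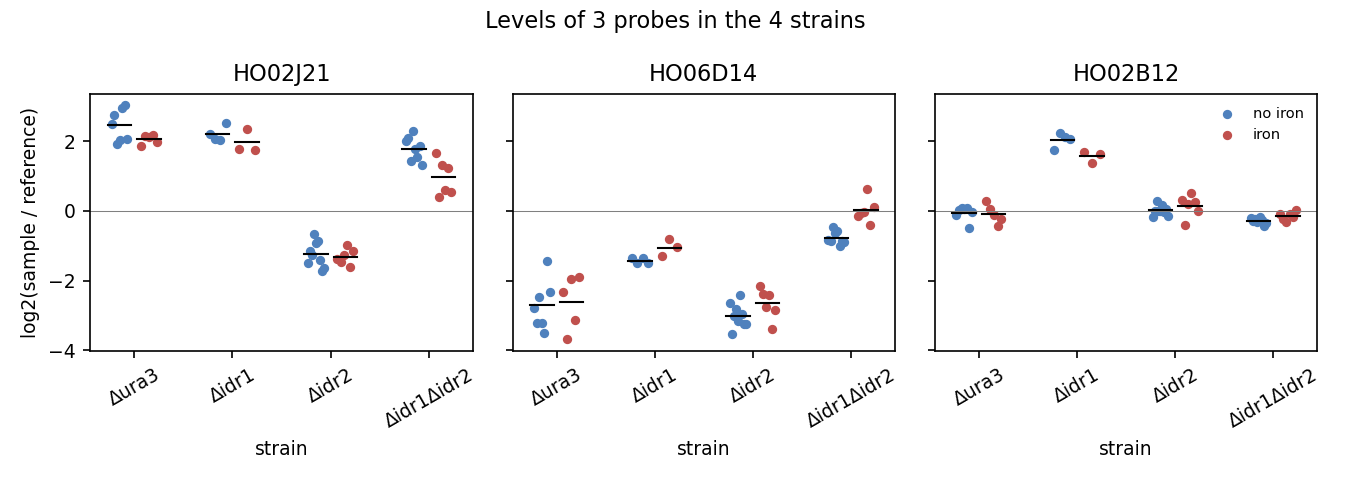
Log2 of sample over reference for 3 probes in the 4 strains, with a point for each sample, without iron in blue and with iron in red, and group means as black lines. HO02J21 lay below 0 in all 15 samples of Δidr2 and above 0 in all others, HO06D14 was highest in the double mutant (0.02 with iron), and HO02B12 stood out in Δidr1 (2.03 without iron).

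The calls of the mutants against the parent overlapped. Without iron, Δidr2 and the double mutant shared 35 probes in the same direction (16 higher, 19 lower) and 0 in opposite directions, where independent lists would share 1.90 and 1.99. Δidr1 and the double mutant shared 54 higher and 30 lower probes, against 22.2 and 17.0 for independent lists, and 21 went in opposite directions. Δidr1 and Δidr2 shared 23, with 2 opposite, against 2.58 higher and 3.65 lower. With iron the pairs, in the same order, shared 11, 9 and 4 probes, with 0, 10 and 1 opposite. Independent lists would share 0.589 higher and 0.425 lower, then 2.65 and 0.32, then 0.37 and 0.045. For Δidr1 and the double mutant with iron, 9 shared against 10 opposite probes show no common direction. In 50 simulations of unchanged groups against the same parent samples at most 1 probe was shared, but such groups have almost no calls to share, so this says little about the part of the shared parent.

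The mutants' changes share the parent samples, which adds to their correlation. The changes of Δidr2 and the double mutant without iron correlated across probes at 0.491, with a covariance of 0.0496, against 0.545 and 0.0176 in simulated unchanged groups. With the parent samples split by replicate, so that each mutant had its own, the correlation was 0.051 and 0.126 for the 2 ways of assigning them, and the covariance 0.00658 and 0.0156. After 0 min the parent's replicate 1 lies in array series 1 to 3 and its replicate 2 in series 4, so the split also sets array series against each other. How much of the drop comes from the shared samples and how much from the array series cannot be told. For Δidr1 and the double mutant it was 0.297 in all samples, and 0.146 and -0.06 after the split; for Δidr1 and Δidr2 it was 0.345, then 0.152 and -0.15. In simulated unchanged groups these pairs had mean correlations of 0.446 and 0.466, above those observed, and covariances of 0.0175 and 0.0174 against 0.0554 and 0.0441 observed. With iron the correlation was 0.548 for Δidr2 and the double mutant, then 0.0344 and 0.104; for Δidr1 and Δidr2 it was 0.154, then 0.0752 and -0.39, and for Δidr1 and the double mutant 0.159, then 0.0715 and -0.29. The simulated correlations with iron were 0.577, 0.482 and 0.481, again above those observed. The covariance was 0.0574 for Δidr2 and the double mutant, and 0.0148 and 0.0195 for the pairs with Δidr1, where the simulated 0.0254 and 0.0253 were larger. With the authors' values the shared probes without iron were 1 for Δidr2 and the double mutant, 21 for Δidr1 and the double mutant and 0 for Δidr1 and Δidr2.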

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

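The tests in this part were chosen after the result was seen, except the share of other Δidr2 probes that moved alike in the double mutant. The iron response of the double mutant differed from that of Δidr2 in 7 probes, 4 with a higher and 3 with a lower response in the double mutant, by a limma test of the difference itself. The authors' values gave 8 and 2, and whether the same probes were among them was not examined. No other setting was run for this contrast. The 8 samples whose dye-exchanged arrays correlated under 0.5 were all of Δidr2, and their part in it was not tested. The clearest was HO05A17, whose response was larger by 1.38 in the double mutant (adjusted p 0.00576). It rose there by 1.47 (SE 0.17, adjusted p 3.25e-06) and changed by 0.09 in Δidr2 (SE 0.16), 0.30 in the parent (SE 0.18) and 0.93 in Δidr1 (SE 0.22), with adjusted p of 0.967, 0.894 and 0.121. Against Δidr1 no probe differed by this test, and 138 had an unadjusted p under 0.05.

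HO02J21 and HO02L21, far below the parent in Δidr2, were not so in the strain labelled as lacking both genes. HO02N21, from the same plate column, went the same way and was chosen after its value was seen, with a level of -0.68 in Δidr2, 0.40 in the parent, 0.77 in Δidr1 and 0.15 in the double mutant. The test between the strains without iron put HO02J21 higher by 2.98 in the double mutant (adjusted p 1.08e-11) and HO02L21 by 1.80 (adjusted p 4.41e-07). Compressed ratios on the dim arrays of the double mutant would pull a negative value towards 0 without crossing it, but HO02J21 was above 0 in 14 of 14 double mutant samples. A difference between array series would vanish within a series, but the difference between Δidr2 and the parent was -3.72 within array series 4. A wrong strain label stays open: 94.2% of 52 other probes called in Δidr2 (without HO02J21, HO02L21 and HO02N21) had the same sign in the double mutant, which a shared deletion and shared parent samples would both give, and the probe of idr2 is not known here. An event in the Δidr2 strain that the double mutant lacks, and a need for Idr1 in the loss, are biological explanations that may hold and were not tested.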

How the results depend on the processing

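The array series as a fixed block, series 4 alone and the fit without 8 poorly agreeing samples were chosen after seeing the data. Unless a construction is named, the cause was not tested. The values are counts of called probes.

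The iron response of the parent (0) was 8 with the replicate block, 4 with the array series as a random block, 41 as a fixed block and 7 in series 4 alone. That of Δidr1 (1) was 6 without background correction (not HO05M05), 2 with median centring, 0 with scaling, 2 with the authors' values, 7 with the replicate block, 15 and 38 with the series as a random and a fixed block, and 6 without the 8 samples. That of Δidr2 (1) was 0 with median centring, scaling, the authors' values and only its own samples, 4 with the replicate block, 5 and 8 with the series as a random and a fixed block, 511 in series 4 alone and 45 without the 8 samples (not HO05K03). That of the double mutant (184) was 318 without background correction, 1.0e+02 (83 risen and 19 fallen) with median centring, 576 with scaling, 77 with the authors' values (60 shared), 315 with the replicate block, 337 and 372 with the series blocks, 664 with only its own samples and 536 in series 4 alone.

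Without iron, Δidr1 (543) gave 313 with median centring, 259 with scaling, 88 with the authors' values, 818 with the replicate block, 264 with the series as a fixed block and 138 with only the samples of the compared strains. Δidr2 (55) gave 122 without background correction, 16 with median centring, 18 with scaling, 5 with the authors' values, 239 with the replicate block, 97 with the series as a fixed block, 15 with only the compared strains, 229 in series 4 alone and 33 without the 8 samples. The double mutant (347) gave 612 with scaling, 524 with the authors' values (146 shared), 638 with the replicate block, 704 and 713 with the series blocks, 573 with only the compared strains and 1019 in series 4 alone.

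With iron, Δidr1 (72) gave 111 without background correction, 40 with median centring, 27 with scaling, 12 with the authors' values, 204 with the replicate block, 128 and 135 with the series blocks and 1 with only the compared strains. Δidr2 (26) gave 15 without background correction, 6 with median centring, 2 with the authors' values, 146 with the replicate block, 8 with only the compared strains, 567 in series 4 alone and 57 without the 8 samples. The double mutant (186) gave 344 with scaling, 408 with the replicate block, 392 and 417 with the series blocks, 315 with only the compared strains and 660 in series 4 alone. The replicate block by construction leaves the spread between time courses out of the error of these strain comparisons.

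The difference of the iron response from the parent (0 in each) was 9 in Δidr1 with the series as a fixed block, and 104 in series 4 alone and 1 without the 8 samples in Δidr2. In the double mutant it was 29 without background correction, 4 without the dimmest probes, 137 with scaling, 9 with the authors' values, 5 with the replicate block, 21 and 52 with the series blocks, 7 with only the compared strains, 40 in series 4 alone and 4 without the 8 samples. Continued limitation (0) was 1 without the dimmest probes and 1 in series 4 alone. The replicate block changed no other count of these comparisons from 0.

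The overlaps without iron fell with median centring to 4 (Δidr1 and Δidr2, 23), 43 (Δidr1 and the double mutant, 84) and 11 (Δidr2 and the double mutant, 35), and with the authors' values to 0, 21 and 1. With iron they were 0 and 2 with median centring (Δidr1 and Δidr2, 4; Δidr2 and the double mutant, 11) and 0, 1 and 0 with the authors' values.

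Leaving out each sample in turn, with a lone remaining sample assumed to vary like the other groups, the iron response ranged from 0 to 1 in the parent, 0 to 1 in Δidr1, 0 to 3 in Δidr2 and 75 to 171 in the double mutant. Against the parent without iron the ranges were 275 to 728 for Δidr1, 28 to 91 for Δidr2 and 237 to 388 for the double mutant; with iron they were 8 to 104, 7 to 52 and 96 to 185. The differences of the iron response stayed at 0 in Δidr1 and Δidr2 and ranged from 0 to 10 in the double mutant, and continued limitation from 0 to 1.

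Of 319 values of named probes under these settings (samples left out in turn not counted), 276 kept their call and 42 lost it with the same sign; the value of HO06A13 in the idr1 mutant against the parent without iron turned to 0.0818 with the authors' values. The mean responses of the double mutant's probes in the other strains kept their sign, but many shrank. With the authors' values, converted from log10 to log2, the risen set was 0.14 in the parent (0.30), 0.21 in Δidr1 (0.42) and 0.07 in Δidr2 (0.24), and the fallen set -0.13 (-0.19), -0.09 (-0.22) and -0.10 (-0.20). With median centring the fallen set was -0.03, -0.11 and -0.14. In series 4 alone the risen set was 0.18 in the parent, whose iron response there covers 20 and 40 min only, and 0.16 in Δidr2. The fit of Δidr1 alone has no residual degrees of freedom and was not run, nor were the tests of gene lists. Spots near background limit the dim probes.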

Other observations

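The test of pairs printed in different dips, the series test in Δidr1 and the counts over other splits were fixed before their results were seen; the other tests in this part were chosen afterwards. Averaged over the 4 strains, a contrast added after seeing the data, iron raised 111 probes and lowered 89 by limma. HO06J23 rose by 1.34 (SE 0.16, adjusted p 6.64e-06) and HO02A05 by 1.02 (SE 0.14, adjusted p 1.94e-05), while HO04C16 fell by 0.75 (SE 0.09, adjusted p 2.90e-06) and HO02M19 by 0.71 (SE 0.15, adjusted p 0.00314). Of the risen and the fallen probes, 78 and 64 were also called in the double mutant alone, which is part of the mean. The mean change of the risen probes was 0.24, 0.49 and 0.58 at 20, 40 and 60 min, and that of the fallen -0.24, -0.37 and -0.45. The authors' values gave 40 risen and 18 fallen probes.

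The double mutant without iron differed from Δidr1 in 691 probes and from Δidr2 in 277. The authors' values turned this order, with 218 higher and 185 lower probes against Δidr1 and 266 and 292 against Δidr2. Against Δidr1, HO05A16 was higher by 1.57 (adjusted p 1.25e-05) and HO04F05 lower, at -3.20 (adjusted p 5.03e-06). Δidr1 and the double mutant share no array series, so that the first of these counts and the array series cannot be told apart. Both counts also set the dim arrays of the double mutant against brighter ones, and the part of this was not tested.

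The calls in Δidr1 without iron were set against the array series, since the parent's difference between its replicate from series 1 or 2 and its replicate from series 4 correlated with the change in Δidr1 (r 0.581 across the 543 called probes, 0.409 across all). That test shares parent samples with the change; at times with no sample in common, r across all probes was 0.596 for the parent's difference at 20 min (series 1 against 4) and 0.121 for that at 60 min (series 2 against 4). A difference between array series is therefore a candidate explanation for part of these calls. It does not cover all of them: of 204 probes called without the samples of series 1, 181 had the same sign within series 1 at 20 min, 88.7% against 63.8% of all probes. With the series as a fixed block 264 probes were called, of which 186 were among the 543, and the share of each cause was not settled.

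In the iron response of the double mutant, probes 2 plate rows apart in a column changed together, at r = 0.326 over 2100 pairs, against -0.02 for probes 1 row apart and 0.01 for 3 rows, and the authors' values gave 0.214, -0.05 and -0.03. Against the parent without iron it was 0.280 in Δidr2 (0.0897 with the authors' values), 0.267 in the double mutant and 0.077 in Δidr1. For 4 rows r was 0.187 in the iron response of the double mutant. Without iron it was 0.219 in Δidr2, 0.275 in the double mutant and 0.276 in Δidr1. Under the printing rule such pairs come from the same pin, and the part of the pin was not tested. Spots printed in the same dip of the pins do not account for the correlation over 2 rows, as pairs printed in different dips correlated at 0.361. Carry-over from dip to dip does not either, with r = 0.0233 between consecutive dips of a pin. A candidate explanation, not tested for want of gene names, is that every second row follows gene order, so that such pairs lie in one operon.

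Other splits of the same samples, within each time, were fitted for every comparison. For the iron response of the double mutant no other split gave as many calls. Its 184 probes were matched by 1 of 100 splits, the real one, with 82 in the highest other. Among the 32 splits that part every numbered pair it was matched by 1, with 50 in the highest other. These splits exchange single times, although the times of an arm come from the same part of a split culture. With whole cultures as units the splits are too few, so chance is not excluded for this response. The double mutant's 347 probes against the parent without iron and 186 with iron were each matched by 1 of 100, with 208 and 71 in the highest others. These splits, and those of the other strain comparisons, exchange single samples although samples of the same number go together in Δidr2 and the double mutant. With whole courses as units the splits are too few. For Δidr1 without iron 1 of 54 splits gave 543, with 264 in the highest other, which exchanges Δidr1 with the parent's replicate 2, all from series 4. For Δidr2 with iron 4 of 100 splits gave 26 or more. The highest, with 216, sets the samples of array series 4 against those of series 1 to 3, so the splits carry the array series and do not settle the 26; with the series as a fixed block the count was 38, 9 higher and 29 lower, of which 7 were among the 26.

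For Δidr2 without iron 5 of 100 splits gave 55 or more, up to 275; these splits too exchange samples across array series and do not settle the 55, which was 97 with the series as a fixed block, 239 with the replicate block and 229 in series 4 alone. Chance could not be excluded for the iron response of Δidr2, of 1 probe, with 26 of 100 splits and up to 637; among 32 splits within pairs 7 gave as many. A count of 0 is reached by every split by construction, so the splits say nothing about chance there: the 54 of the parent's iron response went up to 435, the 100 for each difference of the iron response up to 358 for Δidr1, 410 for Δidr2 and 72 for the double mutant, and the 100 for continued iron limitation up to 34. The highest splits of the iron responses of the parent and Δidr2 set replicate 1 against replicate 2, in Δidr2 array series 3 against 4 and in the parent series 1 to 3 against 4, so they hold a real difference between samples; with the series as a fixed block the iron responses were 41 and 8 probes. For the iron response of Δidr1 (1 probe) the 4 splits are too few, with 0 in the highest other and 1 as large, and likewise the 18 for Δidr1 with iron (72 probes), with 39 in the highest other and 1 as large.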
